A study of Mus musculus with 18 samples.

How the data were processed

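Polyadenylated RNA of mammary epithelial organoids from C57BL/6 mice was measured in 18 libraries of 6 groups, 3 per group, in 2 experiments. Groups were taken from the sample labels: ethanol and estradiol, and DMSO and Torin 1 in the arms D6 and D12. Libraries were stranded, made with an NEBNext Ultra II kit and sequenced as paired ends on a NovaSeq. The sample labels and the series design assign the treatment lengths of 6 and 12 days to the Torin arms in opposite ways, and the arms also carry different batch tags. The series text counts more Torin samples than the 12 used here, and any others were not analysed here.

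The submitters' processing notes name Trim Galore, cutadapt, FastQC, MultiQC, kallisto, DESeq2 and the mouse genome GRCm39, without versions, roles or annotation. For the estradiol experiment the authors deposited estimated counts per gene, of which 32.2% were not whole numbers. For the Torin experiment the authors deposited whole-number counts per gene symbol. For both, the authors also deposited normalized values, a signal made by dividing counts by factors that differ between genes of a library. That signal was used only in alternatives. How reads shared between near-identical genes (ribosomal protein, keratin, Sprr or MHC genes) were assigned is not stated.

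Estimated counts were rounded to whole numbers. The estradiol table held 56691 features, 36085 of them with a count, and that of the Torin experiment 56893 and 37012. Of the estradiol features 39334 had a symbol in the file, 12739 were given a symbol from an identifier table, and 4618 had none. The most abundant estradiol feature, ENSMUSG00000119584.1, had no symbol and took 5.12 to 7.83% of counts in ethanol and 4.20 to 4.85% in estradiol libraries; it is named because of its abundance, after its values were seen.

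Each experiment was fitted separately in R 4.3.3 with edgeR 4.0.16: filterByExpr for low counts, TMM scaling, and the quasi-likelihood test with group means and no covariates, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The words rose, fell and changed refer to genes past it. The filter left 15358 genes in the estradiol and 18112 in the Torin experiment. The comparisons were estradiol against ethanol, Torin against DMSO in D6 and in D12, the difference of these Torin effects (D12 minus D6), and DMSO D12 against D6. No control was shared between the Torin arms or with estradiol. CPM values are counts relative to the TMM-scaled library total, given as mean ± SD of 3 libraries. Log2 fold changes of genes carry the standard error of the fit. A standard error of a list median is taken over its member genes and does not measure the spread between libraries. Where a group held 10 or fewer counts in all, the ratio of counts is given with a 95% counting interval.

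For gene lists, limma 3.58.1 provided camera on the edgeR fit, which compares the members of a list with all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg correction over 32 lists. The lists cover metabolism, growth signalling, the cell cycle, stress responses, and markers of mammary and other cell types. The same test with a correlation estimated from the data was run beside it, and fry, which tests whether a list moves one way on balance and does not compare it with other genes. A list without a call can hold members that passed one by one. Members are counted over all genes tested and adjusted over the list alone.

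The tests, the lists, the alternatives listed first and the rule for named genes were chosen before the data were examined. The rule names, for each treatment comparison, the 6 largest rises and falls among genes past the threshold whose groups do not overlap, with a mean of at least 5 CPM and a symbol other than a predicted gene. It adds 8 genes chosen for estradiol (Pgr, Greb1, Areg, Tnfsf11, Wnt4, Esr1, Ccnd1, Cited1) and 8 for Torin (among them Mtor, Rptor, Rictor, Deptor, Eif4ebp1, Irs2 and Sqstm1). It also adds the 3 members with the lowest p of each list that was called or had at least 3 members past the threshold. For the difference between arms and for DMSO it names the 4 largest each way. Some genes taken by the rule are not reported here. Genes outside the rule are stated as chosen after their values were seen.

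Alternatives were DESeq2 1.42.0, RLE size factors, no filter, a stricter filter (1 CPM in 3 libraries), an adjusted p under 0.01, at least a 2-fold change, a fit of the 2 compared groups alone, the replicate number as a block, limma on log2 of the deposited signal plus 1 (mean at least 10), and each library left out in turn. Added after the data were seen were a fit with the gene-length factors recovered from the deposited tables, omission of the third Torin library of each arm, omission of the most abundant estradiol feature, and list tests with each library left out.

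Replicate numbers showed no clear pairing of libraries in correlations of deviations from the group mean. Between libraries of one number these ranged from −0.0267 to −0.00972 over 3 pairs with estradiol and from −0.0939 to 0.0931 over 18 pairs with Torin. The highest was between the third Torin libraries of the arms, but Torin libraries of different numbers reached 0.161. With 3 libraries per group this check is weak and does not exclude a pairing. The pipeline was tested on simulated data with the observed depth and the fitted spread of each gene. In these data 200 of the genes were changed and the members of a further list raised 1.5-fold. At 2-fold the pipeline recovered 96% of changed genes for estradiol, 70% for Torin D6, 68% for Torin D12, 36% for the difference between arms and 74% for DMSO. At 4-fold these were 100, 98, 94, 78 and 98%. False calls made up 9.79, 4.76, 3.85, 6.19 and 3.12% of calls, so that with estradiol and for the difference between arms they exceeded the nominal 5%. The simulation gave a gene the same spread in all groups of an experiment, and changed far fewer genes than were called in the treatment comparisons. Recovery and false calls may therefore differ in the real data. The spread between replicates at genes with at least 50 counts, as chi-square over degrees of freedom against Poisson noise, was 3.89 to 22.8 in the estradiol experiment, 8.07 to 17.5 in DMSO libraries, 17.7 to 169 with Torin in D6 and 9.49 to 62 with Torin in D12.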

Results

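RNA was sequenced from mammary epithelial organoids of nulliparous C57BL/6 mice in 2 experiments. The first compared 10 nM estradiol, the ligand of the estrogen receptors, with ethanol after 11 days of treatment, in organoids from mice of about 24 weeks. The second compared 100 nM Torin 1, an inhibitor of the mTOR kinase, with DMSO in organoids from mice of about 15 weeks, all collected after 18 days of culture. The Torin experiment has arms named D6 and D12. The sample titles read these as 6 and 12 days of treatment, while the series design gives 12 days for D6 and 6 days for D12. The arms are therefore called D6 and D12 here, and no statement rests on which treatment was longer. The labels also tag the arms as separate batches. With one day of collection, treatments of different length also began on different days of culture if they ran until collection. Batch, length of treatment and its start in culture therefore cannot be told apart. Each group had 3 libraries, for 18 in all, with 20637765 to 24312389 counts per library in the estradiol experiment and 23239364 to 28910688 in the Torin experiment. The spread between replicates was smaller with estradiol (biological coefficient of variation 5.27%) than with Torin (20.2%), so equal fold changes passed the test more readily in the first. What separates the replicates (mouse, culture or well) is not stated, and each p-value measures the spread between these libraries.

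Estradiol raised Pgr, which encodes the progesterone receptor, from 9.39 ± 1.21 to 51 ± 4.55 CPM (mean ± SD, n = 3 per group), a log2 fold change of 2.45 (SE 0.090). Greb1, which encodes a cofactor of the estrogen receptor, rose by a log2 of 4.56 (SE 0.36) from 0.214 ± 0.165 CPM. Of the glycolysis genes 18 of 20 fell, and of the ribosomal protein genes 76 of 77, while 26 of 30 interferon response, 31 of 40 ribosome biogenesis and 20 of 29 S phase genes rose. Areg, which encodes the growth factor amphiregulin, rose by a log2 of 0.45 (SE 0.055), and Ccnd1 (cyclin D1) by 0.28 (SE 0.034). Esr1, which encodes estrogen receptor alpha, fell from 28.4 ± 1.36 to 15 ± 0.845 CPM (log2 −0.92, SE 0.072). Cited1, a transcriptional coactivator gene, fell by a log2 of −2.19 (SE 0.15). Wnt4 did not pass the test (log2 0.11, SE 0.16; adjusted p = 0.639, edgeR's quasi-likelihood test with Benjamini-Hochberg correction). Tnfsf11, which encodes the cytokine RANKL, was too low to be tested, with 4, 5 and 2 counts in the ethanol libraries and 14, 13 and 8 in the estradiol libraries.

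Among the 15358 genes tested with estradiol, 2668 rose and 2552 fell, and 256 of the rises and 368 of the falls were at least 2-fold. The groups did not overlap for 7126 genes (46.4%; 10% by chance for 3 against 3). Genes of largest change are given here and for the Torin arms among those with a mean of at least 5 CPM, groups that did not overlap and a symbol other than a predicted gene; some rarer genes changed as much as these. Within these limits the largest rises with estradiol were of Slc5a5 (the sodium-iodide symporter; log2 5.56, SE 0.21), Enpp2 (autotaxin, which makes lysophosphatidic acid; log2 5.42, SE 0.14, from 2.75 ± 1.39 to 118 ± 1.85 CPM) and Dio2 (a deiodinase that activates thyroid hormone; log2 4.31, SE 0.076). Timp4, a metalloproteinase inhibitor gene (log2 3.46, SE 0.14), Msx2, a homeobox gene (log2 3.10, SE 0.091), and Dmp1, a matrix protein gene (log2 3.09, SE 0.13), followed. Within the same limits the largest falls were of the fibrinogen chain genes Fgb (log2 −5.76, SE 0.067, from 170 ± 2.03 to 3.13 ± 0.331 CPM) and Fgg (log2 −2.97, SE 0.064). Aldh1a1, a retinaldehyde dehydrogenase gene, fell from 24.6 ± 2.29 to 3.24 ± 0.314 CPM. Olfm1 (log2 −2.81, SE 0.11), Bpifb1 (log2 −2.58, SE 0.13) and Masp1, a complement protease gene (log2 −2.52, SE 0.11), also fell.

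**Figure D1:**
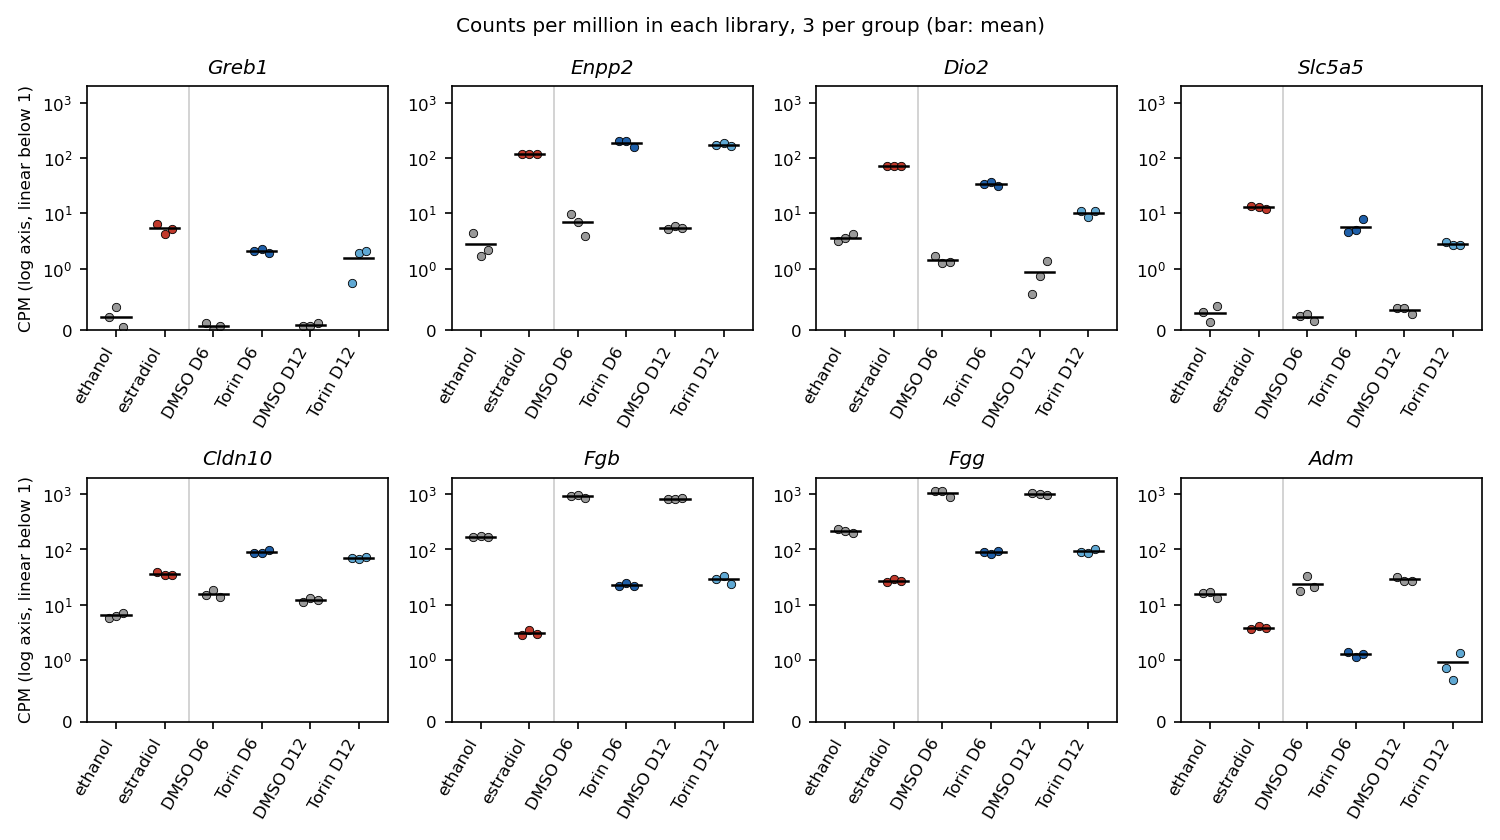
CPM in each library for 8 genes that changed in one direction with estradiol and in both Torin arms, 3 libraries per group; bars mark group means. These 8 genes were picked after their values were seen.

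Of 32 gene lists fixed before the data were examined, camera's competitive test with a preset correlation of 0.01 called 9 with estradiol. None of the 9 held with a correlation estimated from the data. Of 77 ribosomal protein genes, 76 fell and none rose, and the counts were equal when adjusted over the list alone (median log2 −0.318; adjusted p = 0.382 with an estimated correlation). Their share of all counts was 5.98 to 6.41% in ethanol and 5.16 to 5.44% in estradiol libraries. Glycolysis genes fell in 18 of 20 cases, also when adjusted over the list alone (median log2 −0.441; adjusted p = 0.382 with an estimated correlation), among them Gapdh (log2 −0.54, SE 0.034), Aldoa (−0.51, SE 0.035) and Pfkp (−0.67, SE 0.046). Of 25 genes of FOXO and insulin receptor feedback, 14 fell and 2 rose (14 and 3 adjusted over the list alone; median log2 −0.212; adjusted p = 0.382 with an estimated correlation). Txnip fell by a log2 of −0.87 (SE 0.041) and Pik3ip1, an inhibitor of PI3K, by −0.74 (SE 0.048).

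The 6 lists called upward with estradiol were led by the interferon response, in which 26 of 30 genes rose and none fell, also when adjusted over the list alone (median log2 0.583; adjusted p = 0.384 with an estimated correlation). Oasl1 rose by a log2 of 0.95 (SE 0.099) and Gbp2 by 0.60 (SE 0.060). In ribosome biogenesis 31 of 40 genes rose and 1 fell (32 and 1 adjusted over the list alone; median log2 0.265; adjusted p = 0.382 with an estimated correlation), among them Nop56 (log2 0.58, SE 0.046) and Ddx21 (0.53, SE 0.041). In S phase 20 of 29 rose and 1 fell (22 and 2 adjusted over the list alone; median log2 0.248; adjusted p = 0.382 with an estimated correlation), among them Ccne1 (log2 0.78, SE 0.096) and the replication helicase gene Mcm5 (0.46, SE 0.056). In the unfolded protein response 11 of 20 rose and 1 fell (median log2 0.153; adjusted p = 0.382 with an estimated correlation), and in extracellular matrix and TGF-beta response 12 of 26 rose and 3 fell (median log2 0.164; adjusted p = 0.522 with an estimated correlation). Calr rose by a log2 of 0.38 (SE 0.044) and Tnc by 0.82 (SE 0.056). In the inflammatory response 12 of 22 rose and 3 fell (median log2 0.164; adjusted p = 0.382 with an estimated correlation), with Ccl2 up by a log2 of 0.99 (SE 0.090) and Lcn2 down by −0.29 (SE 0.033). For these 3 lists the counts adjusted over the list alone were equal. The inflammatory call was lost without the third ethanol library (median log2 0.154).

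The other 23 lists were not called with estradiol. Of 26 measured estrogen response genes, 10 rose and 8 fell, with Egr3 up (log2 1.31, SE 0.060) and Xbp1 down (−0.78, SE 0.051). The hormone-sensing luminal markers had 6 rises and 5 falls among 15, with Stat5a up (log2 1.11, SE 0.045). Without the third estradiol library both lists were called upward (medians 0.0851 and 0.0666). Luminal progenitor markers had 6 and 6 among 14, with Ltf, the lactoferrin gene, down (−1.43, SE 0.088). Of 22 basal myoepithelial markers 5 rose, Krt15 most clearly (log2 1.24, SE 0.096), and 9 fell, Lmod1 among them (−1.32, SE 0.13). Of 12 milk synthesis genes 6 fell, with the casein gene Csn1s1 at −0.97 (SE 0.076), while the bile salt lipase gene Cel rose (log2 4.29, SE 0.28). Of 15 squamous keratinization genes 5 rose and 5 fell, with Krt4 at 6 counts in all ethanol libraries together and 215 in the estradiol libraries (ratio 38.8, 95% counting interval 17.5 to 107). Fibroblast markers had 8 rises and 3 falls among 15 (median log2 0.396), with Col1a1 up (log2 0.61, SE 0.057) and Col14a1 down (−0.78, SE 0.087), and were called upward without the second ethanol library (median 0.432) or the third estradiol library (0.315). Pan-luminal markers had 6 rises and 4 falls among 16, with Epcam down (−0.26, SE 0.034).

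Metabolic and signalling lists without a call under estradiol also held single large changes. Fatty acid synthesis had 3 rises and 9 falls among 18 (Scd1 log2 −0.54, SE 0.040), cholesterol synthesis 8 and 4 among 25 (Stard4 −0.32, SE 0.047), and ATF4 and amino acid supply 11 and 9 among 30 (the amino acid transporter gene Slc7a5 0.97, SE 0.061). The mTOR pathway components had 10 rises and 5 falls among 32, with Deptor, which encodes an mTOR-binding inhibitor, down (−0.37, SE 0.037). Growth factors and Notch or Wnt signals had 10 and 6 among 25, with Igfbp3 up (log2 1.45, SE 0.087) and Igf1 down (−1.61, SE 0.15). NRF2 targets had 7 and 6 among 16, with G6pdx up (log2 1.00, SE 0.042) and Nqo1 down (−0.60, SE 0.047), and p53 targets 8 and 4 among 20. Lysosome genes had 6 rises and 10 falls among 40, and autophagy genes 6 and 4 among 32, with Bnip3 down (log2 −0.95, SE 0.048). Mitosis had 2 rises and 1 fall among 25, oxidative phosphorylation 2 and 7 among 36, and mitochondrially encoded genes 1 and 5 among 13. Few markers of immune (4 of 18), endothelial (5 of 13) and adipocyte cells (4 of 13) were measured, with 1, 0 and 2 rises and 1, 1 and 1 falls. Median, mean and test differed in sign for the lysosome, luminal progenitor and pan-luminal lists.

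Torin in the D6 arm lowered all 20 glycolysis genes and 24 of 25 mitosis genes and raised 39 of 40 ribosome biogenesis genes. Ndufa4l2, a mitochondrial protein gene induced by hypoxia, fell from 117 ± 16.7 to 0.29 ± 0.122 CPM (log2 −8.63, SE 0.27, n = 3 per group). Krt4, which encodes a keratin of stratified epithelia, rose from 6 counts in all DMSO libraries together to 1164 with Torin (ratio 180, 95% counting interval 82.7 to 493). Of the mTOR pathway genes named before the data were examined, Deptor (log2 −0.56, SE 0.088) and Eif4ebp1, a translation repressor gene (−0.72, SE 0.11), fell. Rictor (log2 −0.0065, SE 0.11) and Irs2 (0.034, SE 0.18) did not pass. Mtor (log2 0.28, SE 0.15) did not pass either, but did at a log2 of 0.45 without the third Torin D6 library. Rptor (0.31, SE 0.12) and Sqstm1 (0.28, SE 0.14) did not pass, but did at 0.40 and 0.39 without the second Torin D6 library.

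Among the 18112 genes tested in the D6 arm, 3585 rose and 3503 fell, and 1321 of the rises and 1570 of the falls were at least 2-fold. The groups did not overlap for 8783 genes (48.5%; 10% by chance). Among genes with a mean of at least 5 CPM and no overlap, the largest rises after Krt4 were of the protease genes Gzme (log2 5.88, SE 0.35) and Mcpt8 (log2 5.62, SE 0.45), of Soga3 (from 0.762 ± 0.238 to 41 ± 22.2 CPM), of the growth factor gene Bmp4 (log2 5.05, SE 0.44) and of the exonuclease gene Trex2 (log2 4.91, SE 0.32). Within the same limits the largest falls after Ndufa4l2 were of the adenosine receptor gene Adora2a (796 counts in DMSO and 5 with Torin; ratio 0.00584, 95% counting interval 0.00189 to 0.0137) and the MHC class II gene H2-Ab1 (log2 −7.14, SE 0.25). Gpr15lg (log2 −7.00, SE 0.35), Mgarp, a mitochondrial protein gene (−6.76, SE 0.22), and Ptgdr, a prostaglandin receptor gene (−5.80, SE 0.36), followed.

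Camera called 13 of the 32 lists in the D6 arm, and 5 of these calls held with an estimated correlation: glycolysis, ribosome biogenesis, luminal progenitor markers, extracellular matrix and TGF-beta response, and fibroblast markers. The 20 falls of glycolysis genes stood at a median log2 of −1.44, with the lactate transporter gene Slc16a3 at −5.77 (SE 0.14) and Pfkfb3 at −2.92 (SE 0.13). Of the 40 ribosome biogenesis genes 39 rose over all genes and 40 adjusted over the list alone (median log2 1.01), with Ddx21 at 1.46 (SE 0.083) and Ftsj3 at 1.13 (SE 0.068). Of 16 fibroblast markers 15 fell, and 16 adjusted over the list alone (median log2 −1.63), among them Col1a1 (−2.14, SE 0.16) and Fbln1 (−2.06, SE 0.097). Of 26 matrix and TGF-beta genes 17 fell and 4 rose, also adjusted over the list alone (median log2 −0.821), with Tgfbi at −4.85 (SE 0.19) and Loxl2, which encodes a collagen cross-linking enzyme, at −2.37 (SE 0.16). Of 14 luminal progenitor markers 9 fell and 2 rose, also adjusted over the list alone (median log2 −0.884), with Tspan8 at −2.35 (SE 0.086) and the Notch target Hey1 at −2.10 (SE 0.076). Glycolysis counts were equal when adjusted over the list alone.

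The 8 other D6 calls were lost with an estimated correlation. Interferon response genes fell in 29 of 30 cases (median log2 −2.42; adjusted p = 0.217 with an estimated correlation), with the immunoproteasome genes Psmb9 at −2.41 (SE 0.18) and Psmb8 at −1.97 (SE 0.13). Mitosis genes fell in 24 of 25 cases (median log2 −1.05; adjusted p = 0.0613 with an estimated correlation), with Mki67, the Ki-67 gene, at −1.30 (SE 0.12) and Ccnb2 at −1.62 (SE 0.14). Inflammatory response genes rose in 13 and fell in 2 of 23 cases (median log2 0.546; adjusted p = 0.217 with an estimated correlation), led by the cytokine genes Cxcl5 (3.19, SE 0.24) and Csf3 (2.24, SE 0.11). For these 3 lists the counts adjusted over the list alone were equal. Of 20 p53 targets 12 rose and 1 fell (13 and 1 adjusted over the list alone; median log2 0.37; adjusted p = 0.149 with an estimated correlation), with Bax, a gene of cell death, at 1.09 (SE 0.080). Of 20 fatty acid synthesis genes 8 fell and 2 rose (9 and 3 adjusted over the list alone; median log2 −0.365; adjusted p = 0.0946 with an estimated correlation), with Acss2 at −2.09 (SE 0.097). Of 12 milk synthesis genes 6 fell and 1 rose (8 and 1 adjusted over the list alone; median log2 −0.798; adjusted p = 0.152 with an estimated correlation), with the mucin gene Muc1 at −2.85 (SE 0.20). Squamous keratinization genes fell in 8 and rose in 2 of 18 cases (9 and 2 adjusted over the list alone; median log2 −1.33; adjusted p = 0.457 with an estimated correlation), and their call was lost without the first Torin D6 library (median log2 −1.05). Of 77 ribosomal protein genes 22 rose and none fell (14 and none adjusted over the list alone; median log2 0.38; adjusted p = 0.747 with an estimated correlation), a call lost without the third Torin D6 library (median log2 0.148).

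Lists without a call in the D6 arm included the mTOR pathway components, with 11 rises and 4 falls among 33. Rragd, a nutrient-sensing GTPase gene, rose by a log2 of 3.25 (SE 0.25), and Ddit4, which encodes an inhibitor of mTOR complex 1, fell (−1.01, SE 0.11). Cholesterol synthesis had 12 rises and 5 falls among 25 (Hsd17b7 log2 0.85, SE 0.087), and ATF4 and amino acid supply 8 and 9 among 30, with Phgdh up (1.80, SE 0.077) and Trib3 down (−1.43, SE 0.11). Lysosome genes had 13 rises and 9 falls among 40, with the protease gene Ctsd up (0.80, SE 0.073) and the lipase gene Lipa down (−1.80, SE 0.11). Autophagy genes had 3 and 3 among 32, with Bnip3 down (−4.12, SE 0.20). Estrogen response genes had 11 rises and 5 falls among 27, hormone-sensing markers 4 and 6 among 15, with Areg up (2.05, SE 0.13) and Esr1 down (−1.24, SE 0.11). Basal markers had 5 and 5 among 22, with Krt5 down (−3.19, SE 0.11), and pan-luminal markers 8 and 3 among 16, with Krt18 up (0.73, SE 0.095). NRF2 targets had 9 and 3 among 17, with Gsta4 up (2.99, SE 0.21). Growth factors and Notch or Wnt signals had 9 and 4 among 26, with Igf1 down (−3.41, SE 0.099). FOXO and insulin receptor feedback had 3 rises and 8 falls among 25, and was called downward without the third Torin D6 library (median log2 −0.40 against 0.0337 with all libraries). S phase had 7 and 5 among 29, oxidative phosphorylation 9 and 3 among 36, mitochondrially encoded genes 1 and 2 among 13, and the unfolded protein response 8 and 1 among 20. Immune, endothelial and adipocyte markers had 1, 1 and 2 rises and 3, 2 and 2 falls among 5, 5 and 6. Median, mean and test differed in sign for the ATF4, FOXO, mitochondrially encoded and hormone-sensing lists.

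Torin in the D12 arm lowered 19 of 20 glycolysis genes and all 25 mitosis genes and raised 32 of 40 ribosome biogenesis genes. Krt4 rose again, from 5 counts in all DMSO libraries together to 1065 (ratio 231, 95% counting interval 98.6 to 713). Fgb fell from 832 ± 30.2 to 28.7 ± 4.28 CPM (log2 −4.86, SE 0.12, n = 3 per group), and Adm, which encodes the vasodilator adrenomedullin, by a log2 of −4.89 (SE 0.29). Eif4ebp1 fell (−0.62, SE 0.11), and Rictor, which encodes a subunit of mTOR complex 2, fell by a log2 of −0.35 (SE 0.11). The Rictor call was lost without the first or second DMSO library (log2 −0.29 and −0.34), without the second or the third Torin library (−0.27 and −0.35), and without a filter on low counts. Mtor (log2 0.037, SE 0.15), Rptor (0.11, SE 0.13) and Irs2 (−0.33, SE 0.18) did not pass. Sqstm1 (−0.17, SE 0.14) did not pass either, but did at −0.29 without the third Torin libraries of both arms. Deptor did not pass (−0.17, SE 0.088), but did at −0.51 with gene-length factors.

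Of the 18112 genes tested in the D12 arm, 1955 rose and 2637 fell, and 506 of the rises and 902 of the falls were at least 2-fold. Without the third Torin libraries of both arms 3243 rose and 3338 fell. With each arm fitted alone 5186 genes were called in D12 and 5687 in D6. With all libraries the groups did not overlap for 7914 genes (43.7%; 10% by chance). Among genes with a mean of at least 5 CPM and no overlap, the largest rises after Krt4 were of Enpp2 (log2 4.98, SE 0.27, from 5.52 ± 0.272 to 174 ± 8.96 CPM), the noradrenaline transporter gene Slc6a2 (3.52, SE 0.24) and Dio2 (3.42, SE 0.25). Timp4 (2.65, SE 0.34) and the tight junction gene Cldn10 (2.53, SE 0.11) followed. Within the same limits the largest falls were of Sprr2a2, a gene of the cornified envelope (log2 −5.03, SE 0.46), then Adm, Fgb, the protease-like gene Prss35 (−4.53, SE 0.21), the cystatin family gene Cstdc5 (−4.48, SE 0.33) and Gpr15lg (−3.77, SE 0.26).

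Camera called 14 of the 32 lists in the D12 arm, and glycolysis, ribosome biogenesis and mitosis held with an estimated correlation. Glycolysis stood at a median log2 of −1.17, with Pgk1 at −1.58 (SE 0.084) and Slc16a3 at −2.16 (SE 0.12). Mitosis stood at −1.22, with the kinase gene Aurka at −1.80 (SE 0.14) and Tpx2 at −1.27 (SE 0.10). For both lists the counts adjusted over the list alone were equal. In ribosome biogenesis 32 genes rose and none fell (36 and none adjusted over the list alone; median log2 0.63), with Rrp12 at 1.52 (SE 0.13). Interferon response genes fell in 21 of 30 cases, 24 adjusted over the list alone (median log2 −1.14; adjusted p = 0.332 with an estimated correlation), with Tap1 at −0.98 (SE 0.12). Squamous keratinization genes fell in 11 and rose in 2 of 18 cases (13 and 2 adjusted over the list alone; median log2 −2.14; adjusted p = 0.129 with an estimated correlation), with Krt16 at −3.45 (SE 0.25) and Sprr1a at −2.97 (SE 0.25). Of the 77 ribosomal proteins, transcripts of 9 rose and of none fell (4 and none adjusted over the list alone; median log2 0.149; adjusted p = 0.84 with an estimated correlation). That call was lost without the third DMSO D12 library (median log2 0.0822), and without the third Torin D12 library the median turned to −0.060.

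The 8 remaining calls of the D12 arm were all downward and were lost with an estimated correlation. Of 25 cholesterol synthesis genes 12 fell and 2 rose, also adjusted over the list alone (median log2 −0.323; adjusted p = 0.101 with an estimated correlation), with Hmgcs1 at −0.67 (SE 0.064). Of 20 fatty acid synthesis genes 8 fell and none rose (10 and 1 adjusted over the list alone; median log2 −0.224; adjusted p = 0.129 with an estimated correlation), with Acss2 at −1.21 (SE 0.093). Of 30 genes of ATF4 and amino acid supply 11 fell and 2 rose (16 and 2 adjusted over the list alone; median log2 −0.316; adjusted p = 0.219 with an estimated correlation), with the serine synthesis gene Psat1 at −1.38 (SE 0.12). Of 20 p53 targets 9 fell and 1 rose, also adjusted over the list alone (median log2 −0.20; adjusted p = 0.129 with an estimated correlation), with Cdkn1a, the p21 gene, at −1.15 (SE 0.10). Of 40 lysosome genes 17 fell and 2 rose, also adjusted over the list alone (median log2 −0.158; adjusted p = 0.271 with an estimated correlation), with Psap at −0.73 (SE 0.085). Of 26 matrix and TGF-beta genes 12 fell and 2 rose (13 and 3 adjusted over the list alone; median log2 −0.371; adjusted p = 0.182 with an estimated correlation). Luminal progenitor markers fell in 7 and rose in 1 of 14 cases (7 and 2 adjusted over the list alone; median log2 −0.352; adjusted p = 0.129 with an estimated correlation), with Ltf at −1.70 (SE 0.16). Pan-luminal markers fell in 8 of 16 cases and none rose (9 and none adjusted over the list alone; median log2 −0.399; adjusted p = 0.448 with an estimated correlation), with Elf3, an epithelial transcription factor gene, at −0.71 (SE 0.13).

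Among the lists without a call in the D12 arm, fibroblast markers had 2 rises and 3 falls among 16 (median log2 −0.0383), with Col14a1 up (0.81, SE 0.11) and Fbln1 down (−1.30, SE 0.094). Estrogen response genes had 7 rises and 6 falls among 27, with the chemokine gene Cxcl12 up (1.33, SE 0.087), and hormone-sensing markers 4 and 5 among 15, with Pgr up (2.00, SE 0.23). Basal markers had 5 and 5 among 22, with the oxytocin receptor gene Oxtr up (1.41, SE 0.12), and milk synthesis 2 and 3 among 12, with Cel up (4.05, SE 0.33). Inflammatory response genes had 8 rises and 4 falls among 23, with Ptgs2, the inducible cyclooxygenase gene, down (−1.81, SE 0.22), and were called upward without the first or second Torin library (medians 0.229 and 0.227). Growth factors and Notch or Wnt signals had 5 and 5 among 26, with Igf1 down (−2.45, SE 0.095). The mTOR pathway components had 3 rises and 5 falls among 33, with Ddit4 down (−2.03, SE 0.11), and FOXO and insulin receptor feedback 2 and 6 among 25, with the superoxide dismutase gene Sod2 up (1.16, SE 0.080). Autophagy had no rises and 7 falls among 32, S phase 6 and 7 among 29, with Tyms up (1.07, SE 0.099), oxidative phosphorylation 5 and 1 among 36, and mitochondrially encoded genes 1 and 3 among 13, called downward without the first DMSO library (median −0.292), the first Torin library (−0.295) or the third Torin library (−0.471). NRF2 targets had 1 rise and 5 falls among 17, called downward without the third Torin library (median −0.256), and the unfolded protein response 3 rises among 20. Immune, endothelial and adipocyte markers had 0, 0 and 1 rises and 2, 1 and 1 falls, and immune markers were called downward without the second DMSO library (median −0.873). Median, mean and test differed in sign for the mTOR component, S phase, hormone-sensing and milk lists.

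**Figure D2:**
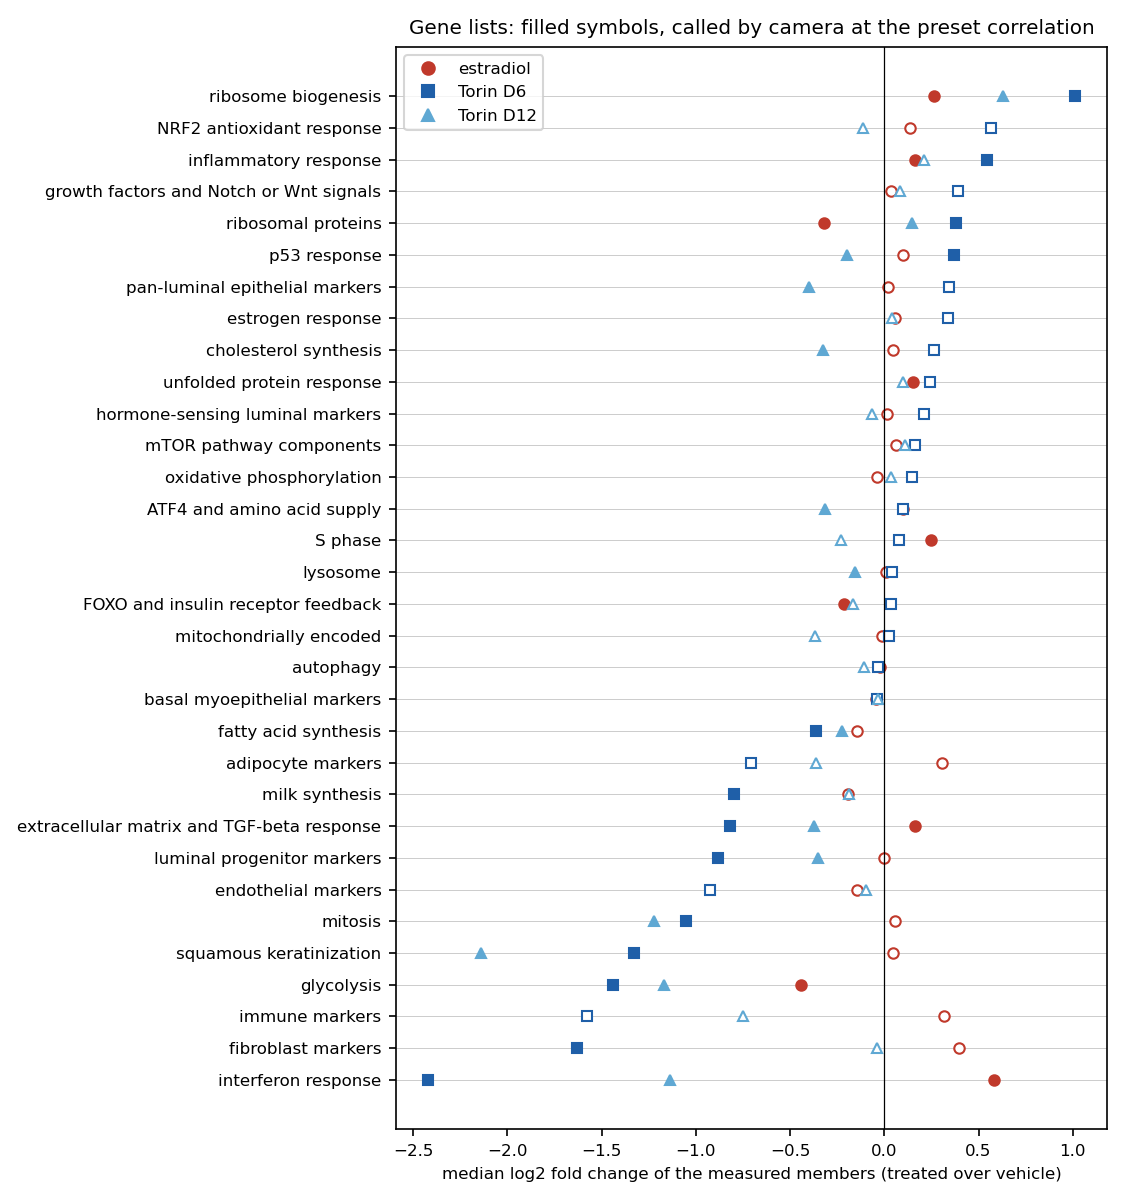
Median log2 fold change of the measured members of each of 32 gene lists with estradiol and in both Torin arms. Filled symbols mark lists called by camera at the preset correlation.

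The Torin effects of the arms differed for 1917 genes when the difference itself was tested (effect in D12 minus effect in D6), with 911 positive and 1006 negative. Ndufa4l2 (log2 difference 5.76, SE 0.33), Adora2a (4.51, SE 0.53), Mgarp (4.41, SE 0.27) and Slc16a3 (3.61, SE 0.17) fell in both arms and fell less in D12. The mesothelin gene Msln (log2 difference −6.68, SE 0.54), Dynap (−5.25, SE 0.60) and the steroid-metabolizing gene Akr1c18 (−4.58, SE 0.22) rose in D6 and fell in D12, and Soga3 (−4.85, SE 0.82) rose in D6 and did not pass in D12. Of the 1917 genes, 901 had effects of opposite sign, 173 of them past the threshold in both arms, 855 (44.6%) had a smaller effect of the same sign in D12, and 161 a larger one. Without the third DMSO D6 library the count was 1219, and without the third Torin libraries of both arms together 3308.

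Camera called 14 lists for the difference between the arms, and 4 of these held with an estimated correlation. Fibroblast markers, of which 15 fell in D6 and 3 in D12, differed upward (13 of 16 with a positive difference, 14 adjusted over the list alone; median 1.64), with Col1a1 at 1.71 (SE 0.21). Luminal progenitor markers also differed upward (7 of 14, and 2 downward, also adjusted over the list alone; median 0.497), with Tspan8 at 2.24 (SE 0.12) and Ltf at −4.28 (SE 0.23). Targets of p53 were lower in D12 relative to D6 (16 of 20, also adjusted over the list alone; median −0.96), with Cdkn1a at −1.43 (SE 0.14) and Eda2r at −1.66 (SE 0.13), and so was cholesterol synthesis (12 of 25, 18 adjusted over the list alone; median −0.523), with Hmgcs1 at −0.71 (SE 0.091). The 10 other calls were lost with an estimated correlation. Interferon response differed upward in 6 of 30 genes, 15 adjusted over the list alone (adjusted p = 0.41 with an estimated correlation), matrix and TGF-beta genes in 13 of 26, 16 adjusted over the list alone (adjusted p = 0.0891 with an estimated correlation), and milk synthesis in 4 of 12, also adjusted over the list alone (adjusted p = 0.0891 with an estimated correlation). Glycolysis differed upward in 6 of 20 genes, 7 adjusted over the list alone (adjusted p = 0.275 with an estimated correlation). Inflammatory response differed downward in 9 of 23 genes, 10 adjusted over the list alone (adjusted p = 0.248 with an estimated correlation), and pan-luminal markers in 9 of 16, 10 adjusted over the list alone (adjusted p = 0.275 with an estimated correlation). Ribosome biogenesis differed downward in 12 of 40 genes, 18 adjusted over the list alone (adjusted p = 0.0891 with an estimated correlation), and lysosome genes in 10 of 40, 12 adjusted over the list alone (adjusted p = 0.283 with an estimated correlation). ATF4 targets differed downward in 8 of 30 genes, 10 adjusted over the list alone (adjusted p = 0.283 with an estimated correlation), and NRF2 targets in 5 of 17, 8 adjusted over the list alone (adjusted p = 0.309 with an estimated correlation).

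**Figure D3:**
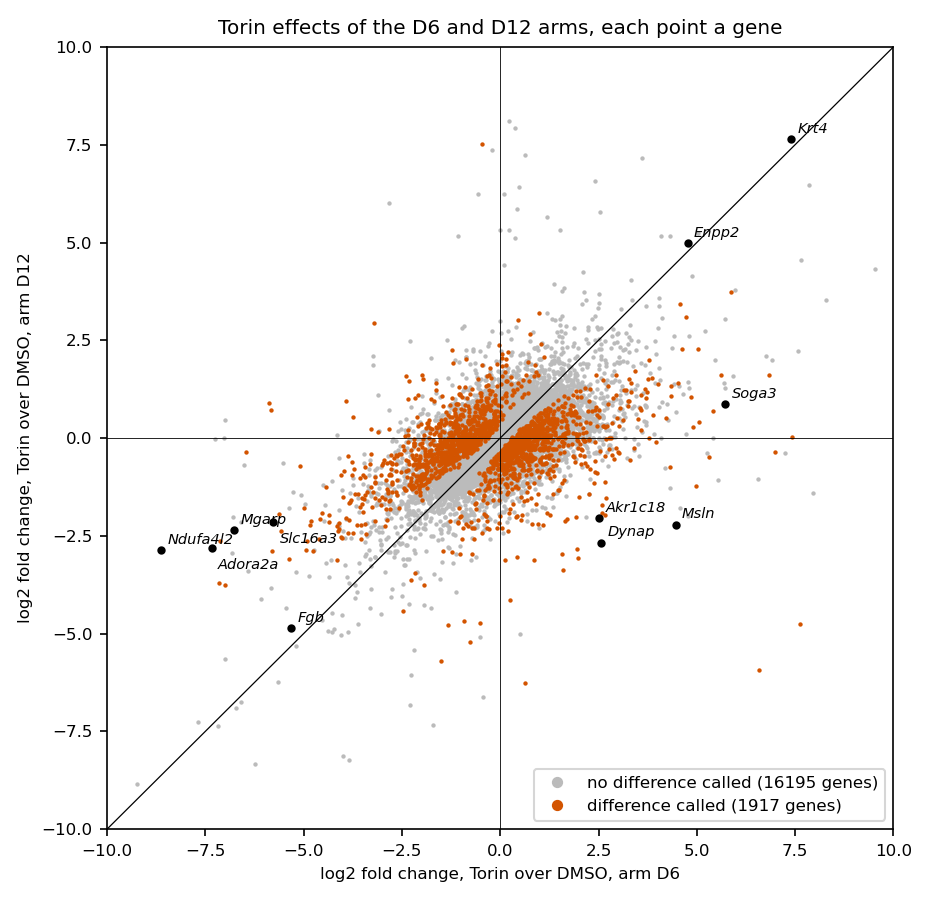
Torin effect on each of 18112 genes in the D6 arm against that in the D12 arm, with the 1917 genes whose effects differed in orange. The line marks equal effects.

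The DMSO groups of the arms gave the background for this difference. In the fit of all Torin and DMSO libraries a single gene, Gm45140, differed between them (log2 −7.82, SE 0.63, D12 over D6; adjusted p = 0.000844, edgeR's quasi-likelihood test with Benjamini-Hochberg correction). It had 717 counts in the D6 and 3 in the D12 DMSO libraries (ratio 0.00374, 95% counting interval 0.000768 to 0.011). At an unadjusted p under 0.05 edgeR gave 732 genes, and DESeq2 called 13 after adjustment. With the DMSO groups fitted alone edgeR gave 1240 genes at that unadjusted p and called 16. The joint fit shares its spread with the Torin libraries, which varied more, so it may miss differences between the DMSO groups. The groups did not overlap for 2201 genes (12.2%; 10% by chance). Camera called 11 lists, 10 of them upward, and none held with an estimated correlation; single omitted libraries left 7 to 12 calls. The largest median was that of squamous keratinization (log2 0.563; adjusted p = 0.303 with an estimated correlation), with no gene past the threshold over all genes and 4 adjusted over the list alone. The interferon call (median log2 0.272; adjusted p = 0.823 with an estimated correlation) turned downward without the first DMSO D12 library (median log2 −0.165). Fibroblast markers were lower in D12 (median log2 −0.165; adjusted p = 0.448 with an estimated correlation), with no gene past the threshold over all genes and 1 adjusted over the list alone. The remaining medians were 0.174 for glycolysis (adjusted p = 0.395 with an estimated correlation), 0.108 for ATF4 and amino acid supply (adjusted p = 0.387 with an estimated correlation), 0.0746 for cholesterol synthesis (adjusted p = 0.387 with an estimated correlation) and 0.138 for pan-luminal markers (adjusted p = 0.448 with an estimated correlation). They were 0.0876 for ribosomal proteins (adjusted p = 0.841 with an estimated correlation), 0.0775 for lysosome (adjusted p = 0.61 with an estimated correlation), 0.0928 for mitosis (adjusted p = 0.633 with an estimated correlation) and 0.348 for immune markers (adjusted p = 0.395 with an estimated correlation).

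Across the 18112 genes, log2 fold changes of the Torin arms correlated with a Pearson r of 0.554 and a Spearman rho of 0.54, where genes are not independent replicates. Both arms called 3260 genes, of which 3087 (94.7%) moved in one direction: 1275 rose in both, against 387 under independence, and 1812 fell in both, against 510. Of the 3260, 2122 (65.1%) changed more in D6, and the median absolute log2 fold change was 0.846 in D6 and 0.686 in D12. Trf, the transferrin gene and the most abundant transcript, took 4.72 to 5.26% of all counts in DMSO libraries, 0.876 to 1.35% with Torin in D6 and 2.91 to 3.45% with Torin in D12. The third Torin library of each arm stood apart, with 3.41% (D6) and 3.35% (D12) of counts on ribosomal protein genes against 2.28 to 2.66% in the other Torin libraries.

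Estradiol and Torin were given in separate experiments with separate controls, and many genes moved alike in both. Of the 13613 genes tested in both, 1371 rose and 1137 fell with estradiol and Torin D6, against 573.8 and 499.9 under independence, and 745 rose and 893 fell with estradiol and Torin D12, against 309.1 and 390.6. Across genes, log2 fold changes correlated with a Pearson r of 0.343 (D6) and 0.347 (D12). In all 3 comparisons 631 genes rose and 735 fell. Examples chosen after their values were seen were Enpp2 (log2 5.42, 4.77 and 4.98 with estradiol, Torin D6 and Torin D12), Dio2 (4.31, 4.58 and 3.42), Slc5a5 (5.56, 4.73 and 3.09), Cldn10 (2.50, 2.52 and 2.53) and Penk, the proenkephalin gene (5.09, 3.49 and 2.48). Greb1 rose from 5 counts in the DMSO libraries to 171 in D6 (ratio 31.8, 95% counting interval 13.4 to 99.2) and from 7 to 130 in D12 (ratio 20.1, 9.5 to 51.1). Shared falls included Fgb (−5.76, −5.33 and −4.86), Fgg (−2.97, −3.57 and −3.43), the vascular ligand gene Apln (−2.11, −4.02 and −2.54) and Adm (−2.01, −4.23 and −4.89). Opposite calls were fewer than under independence: 279 genes rose with estradiol and fell with Torin D6, against 545.5, and 187 fell with estradiol and rose with Torin D6, against 525.7. For Torin D12 these counts were 256, against 426.3, and 95, against 283.2.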

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

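The tests of the third Torin libraries and of treatment length, and the share of larger changes with each arm fitted alone, were chosen after the result was seen; those of library size, of the DMSO groups and of other splits of the libraries were written before it. Each gene value and list median below is the Torin effect in D12 minus that in D6 on the log2 scale, and each gene was singled out because edgeR's test of that difference passed the threshold, each list because camera called it at the preset correlation. Of the 14 list calls, 4 (fibroblast, luminal progenitor, p53 and cholesterol) held with an estimated correlation. In all 1917 genes passed, 88 of them among the genes the naming rule takes for the Torin comparisons; values of 85 follow.

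Transcripts that fell in both arms, and less in D12, were Ndufa4l2 5.76, Adora2a 4.51, Mgarp 4.41, Slc16a3 3.61, Bnip3 1.75, Pfkfb3 0.662 and Pgk1 0.411; the median of the glycolysis list differed by just 0.0951, with 6 of 20 genes past the threshold (adjusted p = 0.275 with an estimated correlation). Ddit4, a stress-induced inhibitor of mTOR complex 1, fell more in D12 (−1.02). The antigen presentation genes H2-Ab1 (3.44), Psmb9 (1.07) and Psmb8 (0.773) also fell less; of 30 interferon response genes 6 differed, all upward (median 1.19; adjusted p = 0.41 with an estimated correlation). Matrix and fibroblast genes that differed upward were Tgfbi 2.63, Col1a1 1.71, Loxl2 1.36, Col14a1 1.26, Fbln1 0.757 and Gsn 0.605, with medians of 0.706 for the matrix and TGF-beta list (13 of 26 upward, 4 downward; adjusted p = 0.0891 with an estimated correlation) and 1.64 for fibroblast markers (13 of 16 upward). Among vascular markers Plvap differed by 1.95 and the VEGF receptor gene Flt1 by −1.27.

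Epithelial markers moved both ways. The luminal progenitor genes Tspan8 (2.24) and Hey1 (1.55) fell in D6 and differed upward, while Ltf rose in D6 and fell in D12 (−4.28); the list median was 0.497. Muc1 (1.5) and Folr1 (1.3) also differed upward, with a milk synthesis median of 0.541 (4 of 12 upward; adjusted p = 0.0891 with an estimated correlation). The luminal genes Krt18 (−1.03) and Cdh1 (−0.895) went the other way, with a pan-luminal median of −0.554 (9 of 16 downward, 1 upward; adjusted p = 0.275 with an estimated correlation). Among basal genes Krt15 differed by 2.85, Krt5 by 2.07, Oxtr by 0.948 and Mylk by 0.656, but Krt17 by −1.52. Of 22 basal myoepithelial markers 6 differed upward and 2 downward, with a median of −0.161 and no call; without the third DMSO D12, the third Torin D6 or the second Torin D12 library camera called the list upward (medians −0.0476, 0.0493 and −0.124), so that median and test differed in sign in 2 of these 3. Of the squamous genes Klk7 differed by 2.01 and Krt16 by −1.29. Neither hormone list was called: of 15 hormone-sensing luminal markers 4 differed upward and 1 downward, and of 27 estrogen response genes 4 and 5. Their members given here are Areg −2.34, Cited1 0.987, Esr1 0.72, Cxcl12 0.795 and Xbp1 0.567.

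Of 20 p53 targets 16 were lower in D12 relative to D6 (median −0.96): Eda2r −1.66, Cdkn1a −1.43, Btg2 −0.92 and Bax −0.462. Lipid synthesis differed by gene: Hmgcs1 −0.714, Hsd17b7 −0.675, Sc5d −0.476 and Elovl7 −0.823, but Fads1 0.981, Acss2 0.877 and Fads2 0.563; the cholesterol median was −0.523, with 12 of 25 genes lower. Of 30 genes of ATF4 and amino acid supply 8 were lower and 3 higher (median −0.365; adjusted p = 0.283 with an estimated correlation), among them Phgdh −1.22, Nupr1 −1, Psat1 −0.579 and Trib3 0.587. Among nutrient-sensing genes Rragd differed by −2.42 and Castor1 by −1.09, and Txnip by 0.773. Of 40 ribosome biogenesis genes 12 differed, all downward (median −0.343; adjusted p = 0.0891 with an estimated correlation), among them Ddx21 −0.50, Ftsj3 −0.41 and Nhp2 −0.368. Of 40 lysosome genes 10 differed, all downward (median −0.288; adjusted p = 0.283 with an estimated correlation), with Ctsd at −0.641.

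Of 17 NRF2 targets 5 were lower and 2 higher (median −0.541; adjusted p = 0.309 with an estimated correlation), with Gsta4 −3.35 and Taldo1 −0.46 but Nqo1 1.09. Of 23 inflammatory response genes 9 differed, all downward (median −0.608; adjusted p = 0.248 with an estimated correlation): Cxcl5 −1.96, Ptgs2 −1.18 and C3 −0.707. Single genes outside these groups were Msln −6.68, Dynap −5.25, Soga3 −4.85, Bmp4 −4.65, Trex2 −4.62, Akr1c18 −4.58, Mcpt8 −4.02, Gzme −2.13, Dio2 −1.16 and Timp4 1.89. Further ones were Gpr15lg 3.23, Ptgdr 2.92, Igf1 0.958, Wnt5a 0.556, Tyms −0.563, Aurka −0.75, Ndufa4 −0.586, Pnpla2 −0.629 and Manf −0.389.

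Torin changed more genes in D6 than in D12 (7088 and 4592, ratio 1.54), and 65.1% of the genes called in both arms changed more in D6. A larger effect in D6 covers only part of the values above. Of the 1917 genes 855 (44.6%) had a smaller effect of the same sign in D12, 901 had effects of opposite sign, and 161 a larger effect in D12. The ratio of counts depends on the fit: with each arm fitted alone D6 had 5687 and D12 5186 called genes (ratio 1.1), while 71.4% of the genes called in both changed more in D6. Library size is argued against, since 1890 genes still differed after all libraries were thinned to the smallest total, with 6993 called in D6 and 4574 in D12. A difference between the DMSO groups is also argued against for the 1917 genes, since the DMSO groups made over 50% of the difference for just 2.76% of them. The third Torin libraries stay open: without them D6 had 7649 and D12 6581 called genes, closer than with all libraries (7088 and 4592), and 61.2% changed more in D6, within the spread of omitting single libraries (57.7 to 71.1%, SD 4.89, lowest without the third Torin D12 library). A longer exposure in one arm may explain the larger changes, but the labels conflict on which was longer and a batch tag follows the arms. All libraries were collected on one day of culture, so the day on which treatment began also differed if it ran until collection. Length of treatment, its start in culture and batch cannot be told apart.

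Other splits of the libraries were run to ask whether chance could give as many calls. Splits that do not part the Torin libraries as labelled mix both arms on each side. A real difference between arms then stays within the groups, so these splits do not show what chance alone gives. For the difference between arms 100 of 200 splits were drawn; 1 of them, the real one, called as many genes (1917, highest other 1759), but this share does not settle the count. The 9 other drawn splits that part the Torin libraries as labelled called 1207 to 1759 genes, and the 90 that do not called 0 or 1, so the way the Torin libraries are parted decides the count. With 10 of the 100 splits parting them as labelled, the real one included, splits of the Torin libraries are too few to give a share under 0.05. For the lists, 7 of the 100 splits called as many as the real one (14, highest other 18). The 90 splits that do not part the Torin libraries as labelled called 0 to 13 lists, and the 9 others that do called 13 to 18. All splits as high as the real one thus kept the real parting of the Torin libraries. Such splits are too few to settle the count of lists, so chance is not excluded for it.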

How the results depend on the processing

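The gene-length factors, the omission of the third Torin library of each arm, the omission of the most abundant estradiol feature and the list tests without single libraries were chosen after seeing the data. No gene called in the reported fit was called in the opposite direction under any alternative. Counts of genes for estradiol and both Torin arms stayed within 1.5 times the reported ones under DESeq2 (4003, 7206 and 5005), limma on the deposited signal (3575, 6166 and 4113), gene-length factors (3601, 6509 and 4057), RLE factors and both filters. Fits of each Torin arm alone called 5687 genes for D6 and 5186 for D12, closer to each other than in the reported fit. Leaving out single libraries gave 4191 to 4828 genes for estradiol, 5595 to 7087 for D6 and 3261 to 4634 for D12. The replicate block, for which the correlations between libraries gave no clear reason, called 4756, 6494 and 4208 genes, and 1513 for the difference between arms.

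Stricter calls lowered the counts by construction. An adjusted p under 0.01 left 3397 genes for estradiol, 4586 for D6, 2733 for D12 and 842 for the difference between arms, and at least a 2-fold change left 624, 2891, 1408 and 941. The difference between arms gave 1219 to 2307 genes with single libraries left out (lowest without DMSO D6 replicate 3) and 3308 without the third Torin library of each arm; the cause was not tested. For DMSO D12 against D6 the count of 1 became 4 without a filter, 16 in a fit of those groups alone and 13 with DESeq2; the cause was not tested.

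The list calls depended on the test. With an estimated correlation 0 lists were called for estradiol, 5 for D6, 3 for D12, 4 for the difference and 0 for DMSO. Fry, which does not compare a list with other genes, called 22 for estradiol, 22 for D6 and 0 for DMSO. Gene-length factors left 7 DMSO lists, and omitting single libraries 7 to 12; the cause was not tested. Other alternatives kept list counts within 1.5 times.

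Medians that changed sign were few. The D6 median of FOXO and insulin receptor feedback (0.0337) ranged from −0.40 without Torin D6 replicate 3 to 0.0833 over single omitted libraries, and was −0.399 without the third library of each arm. The D12 median of ribosomal proteins (0.149) ranged from −0.0598 without Torin D12 replicate 3 to 0.235, and was −0.0422 without the third library of each arm. For the difference between arms basal myoepithelial markers ranged from −0.234 to 0.0493 (highest without Torin D6 replicate 3), and the FOXO list turned to 0.158 without the third library of each arm. The DMSO interferon response list ranged from −0.165 without DMSO D12 replicate 1 to 0.472. The cause was not tested for any of these.

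The correlation of the Torin arms across genes (0.554) was 0.489 to 0.533 with single libraries left out and 0.512 without the third library of each arm. In these fits fewer libraries entered and more genes passed the filter, and these were not separated. The correlation was 0.627 under the stricter filter and 0.64 over called genes alone, where fewer genes enter. Genes called one way in all 3 comparisons numbered 1366, 1193 with DESeq2 and 1707 without the third library of each arm.

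For the 106 genes the naming rule takes for estradiol, 1604 of 1696 alternative values kept their side of the threshold, and 79 of the 92 lost calls came from the 2-fold requirement. Direction was compared only where a gene was called in the reported or the alternative fit, and none of these turned. Values without a call in both fits count as kept even where their sign changed. For D6 1775 of 1832 values of 108 genes were kept in this sense, for D12 1693 of 1751 values of 103 genes, and for the difference 176 of 176 values of 8 genes. Those 8 were the largest differences each way past the threshold, so their calls were likely to be kept. The other genes flagged as differing between arms were not followed for that difference. Small changes were often missed in simulated data, where far fewer genes changed than were called with the treatments. There the estradiol comparison recovered 74% of 1.5-fold changes, D6 36%, D12 32% and the difference between arms 4%.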

Other observations

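All gene lists and all tests of explanations in this part were chosen after the results were seen, apart from the length and GC test and the splits of the libraries. Transcripts induced by low oxygen fell with both treatments. Of 22 such genes outside glycolysis, 18 fell and 1 rose with estradiol (median log2 −0.532), 19 fell and 1 rose with Torin in D6 (median −2.16), and 19 fell and 1 rose in D12 (median −1.78). Egln3, an oxygen sensor gene, stood at log2 −1.61, −4.11 and −2.18 (SE 0.064, 0.12 and 0.11; n = 3 per group), the carbonic anhydrase gene Car9 at −1.15, −4.62 and −2.57, and Vegfa at −1.05, −1.83 and −1.24. Ndrg1 fell by a log2 of −1.26, −3.43 and −2.19, and Stc2 rose in all 3 comparisons (0.18, 0.34 and 0.49). The effect in D12 minus that in D6 passed the threshold upward for 11 of the 22 genes and downward for 1 (median difference 0.505). Among the 11, Angptl4 did not fall in D12 (log2 0.0091). The list was written after falls of some members had been seen, so it was tested without the 4 that had been named as results (Ndufa4l2, Adm, Bnip3 and Ddit4). Of the 18 others 14 fell and 1 rose with estradiol (median log2 −0.477), and 15 fell and 1 rose in each Torin arm (medians −2.12 in D6 and −1.23 in D12).

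Acute phase genes, which the liver secretes in inflammation, split into falls and rises. Fgb, Fgg and Lrg1 fell with estradiol and in both Torin arms (Lrg1 log2 −1.22, −3.85 and −1.65), while the haptoglobin gene Hp (2.00, 0.70 and 1.14) and the serum amyloid gene Saa3 (1.14, 4.02 and 1.38) rose. Of 7 measured members 5 fell and 2 rose with estradiol (median log2 −1.22), and of 8 members 3 fell and 2 rose in each Torin arm. MHC class II genes were looked at because of H2-Ab1, which fell with estradiol and in both Torin arms (log2 −1.66, −7.14 and −3.70), as did the peptide-loading gene H2-DMb1 (−0.40, −1.46 and −0.78). With estradiol these were the only 2 of 5 measured class II genes to pass, and Cd74 stood at 1.05 (SE 0.40; adjusted p = 0.055). In each Torin arm 4 of 6 fell, H2-DMa and Cd74 among them, Ciita did not pass, and H2-Eb1 rose in D6 (1.56, SE 0.34).

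Estradiol and Torin moved many genes in one direction. Abundant genes being called more often in both experiments would, by itself, raise opposite calls too, but these were fewer than under independence (ratio 0.495 for D12 and 0.435 for D6). This argues against abundance as the source of the common direction. Where genes share direction, opposite calls are few in any case, so abundance may still add to the size of the excess over independence. A loss of a few abundant transcripts that scales up the rest would raise shared rises alone, but shared falls also exceeded independence (ratio 2.27 for D6 and 2.29 for D12, beside 2.39 and 2.41 for shared rises). A joint change in the share of fibroblasts would move their markers one way in both experiments. With estradiol 8 of 15 rose and 3 fell (median log2 0.396, SE over member genes 0.161), and in D6 15 of 16 fell (median −1.63, SE 0.21). The directions argue against a joint change for D6, but not strongly. The list was not called with estradiol (camera adjusted p = 0.0541, and 0.618 with an estimated correlation), and these errors do not measure the spread between libraries. The labels name a purification of epithelial cells, but the fibroblasts left after it were not measured. Col1a1, an abundant marker, went from 88.9 to 136 CPM with estradiol and from 407 to 92.3 CPM in D6. A response common to both treatments may explain the sharing, but no test here separates it from other differences between the experiments.

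The fall of glycolysis transcripts with Torin was tested in the same way. After a trend of fold changes with transcript length and GC content was removed, 100% of the median was kept (log2 −1.45, SE over member genes 0.318, in D6 and −1.17, SE 0.146, in D12, for 20 of 20 members). The trend itself was small (SD over genes 0.0499 and 0.0413), and over the glycolysis members it had a median of 0.0241 in D6 and −0.015 in D12, far below their falls. A loss of fibroblasts from the cultures is argued against for D12, where the fibroblast median lay 1.13 above the glycolysis median. For D6 this explanation stays open, since the fibroblast median (log2 −1.63) lay below the glycolysis median (−1.44). A candidate explanation is a fall of hypoxia-inducible transcripts as a whole, since the 18 hypoxia targets outside glycolysis that were left after this omission fell in both arms (larger p = 0.000105, camera with an estimated correlation). That test and the list were still chosen after the data were seen, and oxygen in the cultures was not measured, so the explanation stays a hypothesis.

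Other splits of the libraries were too few, 10 for each of these comparisons, to give a share under 0.05. All but the real one also put libraries of both groups on each side. A real effect then stays within the groups and can lower or leave calls, so these counts do not show what chance alone gives. For estradiol the real split called 5220 genes and the highest other 0, and 9 and 9 lists, with 2 of 10 splits as high. For Torin D6 the values were 7088 and 0 genes, and 13 and 13 lists, with 2 of 10 as high. For Torin D12 they were 4592 and 1 genes, and 14 and 16 lists, with 3 of 10 as high. For DMSO D12 against D6 they were 1 and 0 genes, and 11 and 11 lists, with 2 of 10 as high. For the gene counts, 1 of 10 splits, the real one, reached the real value in each comparison.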
